A study of Rattus norvegicus with 12 samples.

How the data were processed

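Liver RNA of Sprague Dawley rat fetuses at day 19 of gestation was measured on 12 Affymetrix Rat Gene 1.0 ST arrays, 3 each for total and polysome RNA from fed dams and total and polysome RNA from dams fasted for 48 hr from day 17. Per the labels' protocols, total RNA was isolated with guanidine thiocyanate and cesium chloride centrifugation, whereas polysome RNA came from pooled polysome preparations by acid phenol and chloroform, and both were cleaned on columns before amplification and biotin labelling. The values analysed were the deposited intensity values, 1 per probe and array, which the authors made with RMA per the submitters' processing notes; the RMA version is not given in the sources used here. They ran from 3.62 to 21344, which is a linear scale, so tests were run on log2(value + 1), as the design allowed for in case the values were not already logged.

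Of 28826 probes, the platform table listed 15515 and linked 15209 to exactly 1 gene symbol; 306 carried several symbols and 13311 were not listed. The 15209 probes stood for 14497 genes, and 15178 of the probes were matched to current names by Entrez identifier. Where a gene had several probes (494 genes), the brightest on average was used. The planned filter rested on olfactory receptor probes as background, but 59 were named where 100 were needed, so the fallback set in advance was used, the 40th percentile of mean intensity (6.07 log2). This left 10174 genes, and 4323 were left out.

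A cell means model of the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 5.16 prior degrees of freedom). Contrasts compared fasted with fed dams in total RNA and in polysome RNA, the difference between these effects, and polysome with total RNA in each diet. The p values are two-sided and adjusted by Benjamini-Hochberg over genes, with a threshold of 0.05. The median SE of a change was 0.0945 log2, and 0.134 for the difference between effects. Of 36 gene lists fixed from general knowledge, 33 had at least 5 tested members and were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg over lists, and again with a correlation estimated from the data. Camera compares a list with all other tested genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

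The genes named in each comparison followed a rule: the 6 largest rises and 6 largest falls past the threshold whose groups did not overlap; for each list past camera, at most the 8 with the smallest p, the 3 called members that changed most in the direction of the list, or the 2 with the smallest p if none was called; and, in the fasting comparisons and their difference, a fixed set of growth, glucose, lipid and serum protein genes. Genes without an informative symbol were counted but not named. The comparisons, tests, lists, filters and this rule were chosen before the data were examined, as were the alternatives: no filter, arrays centred on their median, quantile normalization, the mean of a gene's probes, trend and robust priors, only the arrays compared, replicate blocks, an estimated correlation and leaving out each array. Leaving out fed polysome 1 and fasted polysome 2 together, using log2 without an added 1 and using each liver as a fixed block were chosen after seeing the data.

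The labels number the arrays 1 to 3 in each group without saying what a number marks. The pairing was therefore checked from the data, by correlating each array's deviations from its group mean. Total and polysome arrays of one diet with the same number correlated at 0.15 to 0.36 in all 6 pairs, and those with other numbers at -0.22 to -0.023 in 12 pairs. Deviations from a group mean cancel within the group, so positive values for equal numbers force negative ones on balance for other numbers. The 12 values are therefore no separate support for a pairing. Fed and fasted arrays with the same number correlated at -0.14 to 0.25. The numbers were therefore taken to pair total with polysome RNA within a diet, which is an inference from the data.

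The fit was tested on simulated data, with changes added to 50 genes of each size in arrays with the real means and spreads but independent genes. It recovered 52% of 1.3-fold, 78% of 1.5-fold and 98% of 2-fold changes between diets in total RNA, and 4%, 56% and 86% of such differences between effects. Of unchanged genes, 0.0602% were called in total RNA and 0.12% for the difference between effects. Of 20 lists shifted by 0.3 log2, 20 were called at either correlation. All genes of these lists were shifted and were independent. The largest median of a real list for fasting in total RNA was 0.208 log2. The 20 of 20 therefore does not say how often real lists would be found. Of 20 unshifted lists 0 were called. Their genes were independent, so this 0 does not give the rate of false calls for the real lists, whose estimated correlations reached 0.58. Wrong splits of the real arrays called up to 16 of the real lists, but these splits kept part of the real difference between groups. They do not give that rate either.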

Results

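Transcript levels were measured in the liver of Sprague Dawley rat fetuses at day 19 of a 21-day gestation. Dams were fed freely or fasted for 48 hr from day 17, a treatment used to restrict fetal growth. From each diet, total liver RNA and polysome RNA were hybridised to separate Affymetrix Rat Gene 1.0 ST arrays. Polysome RNA is the RNA found in sucrose gradient fractions that hold messages carrying several ribosomes. The 12 arrays formed 4 groups of 3: fed total, fasted total, fed polysome and fasted polysome. The labels call the samples biological replicates and name 3 dams per diet. Each array gave 28826 probe intensities with medians from 101.3 to 108.3, and 10174 genes were tested. Across all probes, arrays of the same group correlated at 0.9914 to 0.9961, arrays of one fraction and different diets at 0.9917 to 0.9948, and arrays of different fractions at 0.9816 to 0.988. The number of arrays limits the precision of every comparison. Changes are on the log2(intensity + 1) scale, with the standard error (SE) of the limma fit and n = 3 arrays per group throughout, and adjusted p is Benjamini-Hochberg's.

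The first comparison asked how maternal fasting altered the fetal liver transcriptome. Cpt1a, the gate for entry of long-chain fatty acids into mitochondria, rose 2.41-fold (1.27 ± 0.16 SE log2, limma adjusted p = 0.00289). Scd, the stearoyl-CoA desaturase, fell 2.88-fold (-1.52 ± 0.16, limma adjusted p = 0.00289), and Fasn, the fatty acid synthase, fell 1.85-fold (-0.89 ± 0.10, limma adjusted p = 0.00289). Cyp8b1, a cytochrome P450 of cholic acid synthesis, rose 2.19-fold (1.13 ± 0.14, limma adjusted p = 0.00289). Cyp2b1, a drug-metabolising P450, rose to a mean of 7.94 log2 (limma adjusted p = 0.0104); its fed mean of 5.85 lay under the filter level of 6.07, so no fold is given.

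In total RNA, 105 of 10174 genes passed the threshold, 75 higher and 30 lower after fasting, and 49 of these changed at least 1.5-fold. Their median absolute change was 0.57 log2. The other largest rises were those of Acy3, an aminoacylase (2.33-fold), Cyp2e1, an ethanol- and ketone-oxidising P450 (2.19-fold), and Cpt1b, the muscle-type form of the carnitine palmitoyltransferase (2.19-fold). The other largest falls were those of Cpa1, the pancreatic carboxypeptidase A (3.95-fold), Hsph1, a heat shock chaperone (1.88-fold), Ppil3, a cyclophilin-type prolyl isomerase (1.60-fold), and Ccnb1ip1 (1.54-fold). Cpa1 fell with a wide error (-1.98 ± 0.43 log2, limma adjusted p = 0.0486).

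**Figure D1:**
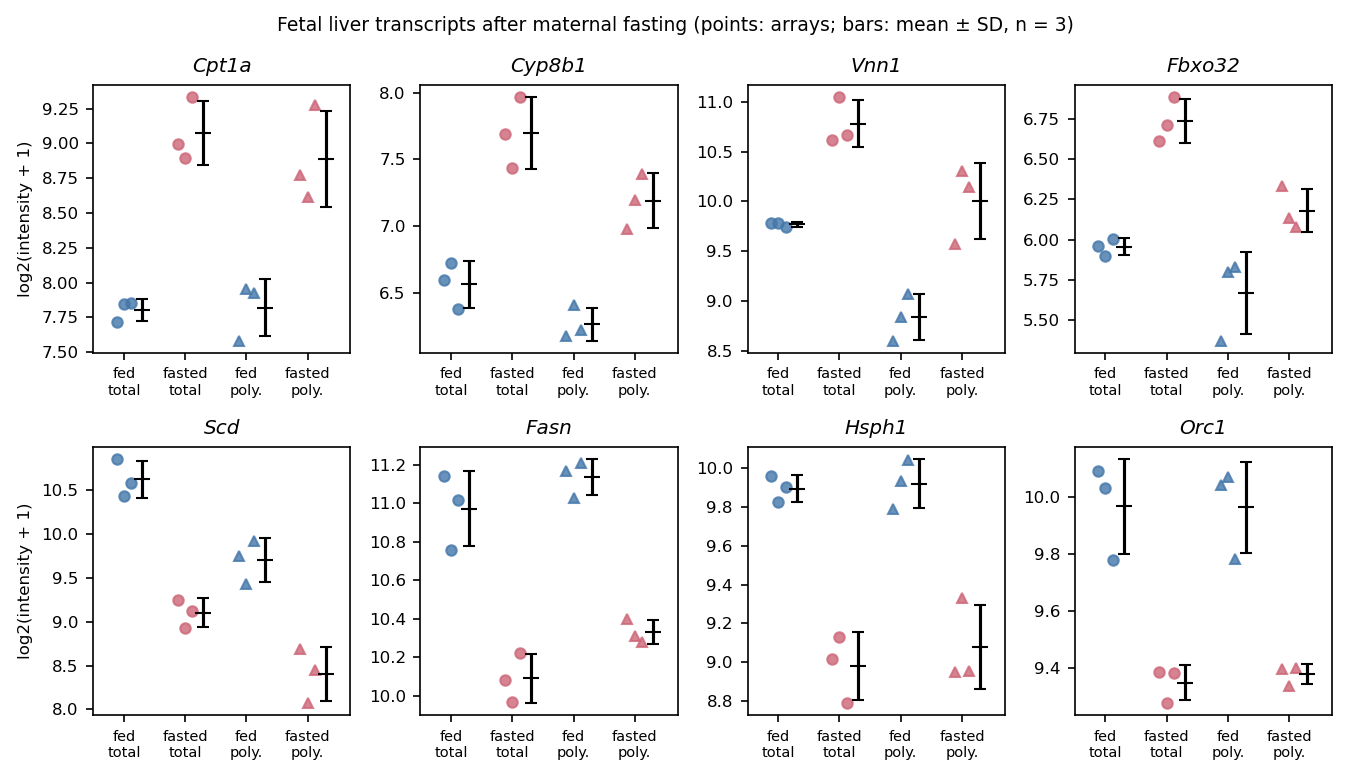
Per-array log2(intensity + 1) of 8 genes in the 4 groups of fetal liver RNA, with circles for total RNA, triangles for polysome RNA, blue for fed and red for fasted dams; bars give the mean ± SD over 3 arrays, and each panel has its own vertical axis, which does not start at 0. All 3 fasted total RNA arrays lie above the 3 fed ones for Cpt1a, Cyp8b1, Vnn1 and Fbxo32 and below them for Scd, Fasn, Hsph1 and Orc1.

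Among the lists fixed in advance, 18 of 33 shifted in total RNA by limma's camera test with a preset correlation of 0.01, 9 up and 9 down. With a correlation estimated from the data, 0 of the 33 lists passed by camera, 8 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0546. Of 39 fatty acid oxidation and ketogenesis genes, 3 rose, Cpt1a, Vnn1, a pantetheinase (2.01-fold), and Acot12, an acetyl-CoA hydrolase (1.32-fold). Adjusted over the list alone, 10 rose, and the list shifted up by camera (adjusted p = 4.14e-09, and adjusted p = 0.101 with an estimated correlation). Of 25 fatty acid and triglyceride synthesis genes, 5 fell, with Scd2 down 1.41-fold beside Scd and Fasn. Adjusted over the list alone, 9 fell, and the list shifted down (camera adjusted p = 5.25e-06, and adjusted p = 0.223 with an estimated correlation). Cholesterol synthesis also shifted down, with 0 of 20 members past the limma threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0064, adjusted p = 0.622 with an estimated correlation, and 0.288 without fed total 3).

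Of 27 hepatocyte maturation genes, 4 rose, among them Cyp8b1, Cyp2e1 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (2.17-fold, limma adjusted p = 0.045). Adjusted over the list alone, 10 rose, and the list shifted up (camera adjusted p = 1.62e-06, and adjusted p = 0.0546 with an estimated correlation). Urea cycle and amino acid catabolism shifted up, with 1 of 33 members higher, or 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.77e-04, and adjusted p = 0.202 with an estimated correlation). Gluconeogenesis shifted up with 0 of 20 members past the limma threshold, and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00412, and adjusted p = 0.114 with an estimated correlation). G6pc1, the glucose-6-phosphatase, and the coactivator Ppargc1a did not pass, at -0.27 ± 0.41 and 0.29 ± 0.13 log2 (limma adjusted p = 0.811 and 0.301). Pck1 lay at 6.14 log2 in fed and 6.12 in fasted livers, near the filter level of 6.07, so its limma adjusted p of 0.975 says little. The serum protein genes Alb and Afp measured -0.02 ± 0.060 and 0.01 ± 0.066 log2 (limma adjusted p = 0.91 and 0.96).

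Ribosome biogenesis shifted down with 0 of 38 members past the limma threshold and 4 lower adjusted over the list alone (camera adjusted p = 1.95e-08, and adjusted p = 0.101 with an estimated correlation). Its members Heatr1 and Nolc1, factors of ribosomal RNA production, measured -0.40 ± 0.094 and -0.33 ± 0.091 log2 (limma adjusted p = 0.0602 and 0.0995). DNA replication and G1/S shifted down with 1 of 48 members lower, and 1 adjusted over the list alone (camera adjusted p = 4.75e-06, and adjusted p = 0.262 with an estimated correlation). That member was Orc1, a subunit of the origin recognition complex, which fell 1.53-fold (limma adjusted p = 0.0129). The proteasome shifted down with 0 of 36 members past the limma threshold and 2 lower adjusted over the list alone (camera adjusted p = 1.61e-06, and adjusted p = 0.148 with an estimated correlation); Psma1 and Psmd7, both proteasome subunits, measured -0.25 ± 0.067 and -0.24 ± 0.065 log2. Growth arrest and FoxO targets shifted up with 1 of 29 members higher, and 1 adjusted over the list alone (camera adjusted p = 2.80e-05, and adjusted p = 0.1 with an estimated correlation). That member was Fbxo32, a ubiquitin ligase subunit of muscle atrophy, which rose to 6.74 log2 (limma adjusted p = 0.0104) from a fed mean of 5.95, under the filter level of 6.07. The mitosis list did not shift (camera adjusted p = 0.611), and Ccnd1, a G1 cyclin, measured -0.14 ± 0.087 log2 (limma adjusted p = 0.475).

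The IGF and growth hormone axis shifted up in total RNA with 0 of 24 members past the limma threshold and 3 higher adjusted over the list alone (camera adjusted p = 0.0393, and adjusted p = 0.148 with an estimated correlation; adjusted p = 0.0603 with the replicate number as a block and 0.133 without fed total 2). Igfbp1 and Igfbp2, binding proteins that restrain insulin-like growth factors, measured 0.51 ± 0.14 and 0.74 ± 0.19 log2 (limma adjusted p = 0.105 and 0.0801). The growth factors Igf1 and Igf2 measured 0.07 ± 0.11 and -0.03 ± 0.065 log2 (limma adjusted p = 0.811 and 0.859). ATF4 amino acid response genes shifted up with 1 of 44 members higher, or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.01e-04, and adjusted p = 0.38 with an estimated correlation); Asns, the asparagine synthetase, measured 0.19 ± 0.070 log2 (limma adjusted p = 0.197). Cytosolic ribosomal proteins, other TOP mRNAs (growth-regulated messages with a pyrimidine start) and oxidative phosphorylation shifted down by camera (adjusted p = 0.00599, 0.0393 and 0.00412, and adjusted p = 0.622, 0.262 and 0.622 with an estimated correlation). In these 3 lists, 0 of 72, 0 of 20 and 0 of 70 members passed the limma threshold, over all genes or adjusted over the list alone. Their calls were lost without single arrays: cytosolic ribosomal proteins and oxidative phosphorylation without fed total 2 (camera adjusted p = 0.173 and 0.17), and other TOP mRNAs without fasted total 3 (0.145).

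In total RNA, of 24 endothelial markers, 4 rose, among them Fcgr2b, an Fc receptor of sinusoidal endothelium (1.52-fold), and the junction proteins Pecam1 (1.35-fold) and Esam (1.32-fold). Adjusted over the list alone, 10 rose, and the list shifted up (camera adjusted p = 7.45e-08, and adjusted p = 0.0756 with an estimated correlation). Pecam1 did not pass with the replicate number as a block (limma adjusted p = 0.0513). Macrophage markers shifted up with 0 of 22 past the limma threshold and 1 higher adjusted over the list alone (camera adjusted p = 0.00323, and adjusted p = 0.222 with an estimated correlation). Neutrophil and monocyte precursor markers shifted down, with 0 of 22 past the limma threshold on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0462, and adjusted p = 0.717 with an estimated correlation; adjusted p = 0.475 without fasted total 1 and 0.0523 with only the arrays compared). Markers of erythroid cells did not shift over 36 genes (limma camera adjusted p = 0.913), with a median of -0.02 log2 and a mean of 0.004. The 15 lists that did not pass had camera adjusted p from 0.107 to 0.944. Genes of the exocrine pancreas were listed only after the fall of Cpa1 was seen. Cpa1 measured 10.1, 7.865 and 8.976 log2 in fed total arrays 1 to 3 and Ctrb1, a chymotrypsinogen, measured 10.55, 7.743 and 8.529, against at most 7.211 and 7.535 in the fasted total arrays.

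The count of genes changed in total RNA depended on single arrays. It was 17 without fasted total 1, 22 without fed total 1, 24 without fasted total 2, 30 without fed total 3, 53 without fed total 2 and 57 without fed polysome 2. It was 57 with no filter on dim probes and 42 with only the arrays compared in the fit. Acy3, Cpt1a, Cyp8b1, Fbxo32, Scd, Fasn and Hsph1 passed in all 12 leave-one-out fits. Without fasted total 1, limma adjusted p was 0.0553 for Cyp2b1, 0.0558 for Ppil3, 0.14 for Acot12, Ccnb1ip1 and Fcgr2b, 0.166 for Pecam1, 0.175 for Cyp7a1 and 0.147 for Cpa1, which passed in 2 of the 12. Without fed total 1, it was 0.0977 for Cyp2e1, 0.128 for Cpt1b, 0.146 for Esam, 0.0649 for Orc1 and 0.0765 for Scd2, and it was 0.0701 for Vnn1 without fasted total 2. With no filter, the adjusted p of Acot12, Ccnb1ip1, Cpa1, Cyp7a1, Esam, Fcgr2b and Pecam1 was 0.0539, 0.0508, 0.057, 0.0557, 0.057, 0.0552 and 0.057. With only the arrays compared, it was 0.0766 for Acot12, 0.0918 for Cpa1, 0.0559 for Cpt1b and Cyp2b1, 0.0739 for Cyp2e1 and Pecam1, 0.0772 for Cyp7a1, 0.0841 for Esam and 0.097 for Fcgr2b. With trend and robust priors, it was 0.111 for Cpa1 and 0.0603 for Cyp7a1.

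The second comparison asked how maternal fasting altered the RNA on polysomes, the translatome. Vnn1 rose 2.25-fold (1.17 ± 0.17 log2, limma adjusted p = 0.0126), Cpt1a 2.09-fold (1.07 ± 0.16, limma adjusted p = 0.0126) and Pdk4, the kinase that turns off pyruvate dehydrogenase, 1.93-fold (0.95 ± 0.18, limma adjusted p = 0.024). Scd fell 2.45-fold (-1.30 ± 0.16, limma adjusted p = 0.00446), Fasn 1.75-fold (-0.81 ± 0.10, limma adjusted p = 0.00446) and the desaturase Scd2 1.70-fold (-0.76 ± 0.084, limma adjusted p = 0.00259). Igfbp1 rose 1.62-fold on polysomes (0.69 ± 0.14, limma adjusted p = 0.0372). The circadian repressor Nr1d2 rose 2.09-fold (1.06 ± 0.13, limma adjusted p = 0.00446).

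In polysome RNA, 205 of 10174 genes passed the threshold, 162 higher and 43 lower after fasting, and 54 of these changed at least 1.5-fold. Higher calls made up 79% of the total, against 68.4% (167 higher, 77 lower) when the arrays were quantile normalized and 87.1% (176 higher, 26 lower) when they were centred on their median. The median absolute change of the calls was 0.48 log2. The other largest rises were those of Doc2a, a calcium sensor of vesicle release (2.14-fold), Cdkl1, a cyclin-dependent kinase-like protein (2.11-fold), and Cyp7a1 (2.09-fold). The other largest falls were those of Hsph1 (1.79-fold), Rab18, a GTPase of lipid droplets (1.51-fold), and Orc1 (-0.59 ± 0.096 log2). Rab18 rested on the brighter of its probes; the other measured 0.17 log2, and their mean gave -0.21 (limma adjusted p = 0.173).

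Of the lists, 13 of 33 shifted in polysome RNA by camera with the preset correlation, 7 up and 6 down. With an estimated correlation, 0 lists passed by camera, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.26. Fatty acid oxidation shifted up, with Cpt1a, Vnn1 and Pdk4 the 3 members past the limma threshold among 39 and 15 higher adjusted over the list alone (camera adjusted p = 2.81e-07, and adjusted p = 0.26 with an estimated correlation). Fatty acid and triglyceride synthesis shifted down with 5 of 25 members lower, and 9 adjusted over the list alone (camera adjusted p = 2.81e-07, and adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis shifted down with 1 of 20 members lower, and 1 adjusted over the list alone (camera adjusted p = 0.0283, and adjusted p = 0.762 with an estimated correlation; adjusted p = 0.35 without fed polysome 3). Growth arrest and FoxO targets shifted up with 3 of 29 members higher, and 7 adjusted over the list alone (camera adjusted p = 0.00107, and adjusted p = 0.26 with an estimated correlation). These members were Pdk4, Tp53inp1, a p53-induced autophagy factor (1.48-fold), and Fbxo32, which rose to 6.18 log2 from a fed mean of 5.67, under the filter level of 6.07. Hepatocyte maturation shifted up with 3 of 27 members higher, and 7 adjusted over the list alone (camera adjusted p = 0.0101, and adjusted p = 0.26 with an estimated correlation). Urea cycle and amino acid catabolism shifted up with 1 of 33 higher, and 5 adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.405 with an estimated correlation; adjusted p = 0.105 without fed polysome 2).

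Of 72 cytosolic ribosomal protein genes, 2 fell on polysomes, and 2 adjusted over the list alone, Rps12 1.41-fold and Rpsa 1.35-fold (camera adjusted p = 0.00107 for the list, and adjusted p = 0.592 with an estimated correlation). Ribosome biogenesis had 0 of 38 members past the limma threshold and 8 lower adjusted over the list alone (camera adjusted p = 3.74e-05, and adjusted p = 0.26 with an estimated correlation). Its members Heatr1 and Tsr1 measured -0.34 ± 0.094 and -0.25 ± 0.067 log2 (limma adjusted p = 0.0711 and 0.0662; Tsr1 passed at 0.0276 without fed polysome 1 and fasted polysome 2). DNA replication and G1/S had Orc1 as its 1 lower member of 48, and 2 adjusted over the list alone (camera adjusted p = 1.18e-04, and adjusted p = 0.405 with an estimated correlation). The 48 mitosis genes did not shift (limma camera adjusted p = 0.72). Gluconeogenesis shifted up with 1 of 20 members higher, or 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0478, and adjusted p = 0.304 with an estimated correlation; adjusted p = 0.0622 with quantile normalization and 0.163 without fasted polysome 2). Ppargc1a measured 0.54 ± 0.13 log2 (limma adjusted p = 0.0511; 0.0319 with the replicate number as a block, 0.0466 with the liver as a random block, 0.0478 with centred arrays, 0.0375 with trend and robust priors and 0.0267 without fed polysome 1 and fasted polysome 2). G6pc1 measured 0.93 ± 0.41 log2 (limma adjusted p = 0.212), and 0.36 without fasted polysome 3 (0.609). Pck1 lay at 5.98 log2 in fed livers, under the filter level of 6.07, and at 6.12 in fasted livers (limma adjusted p = 0.736).

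Igf1, Igf2 and Igfbp2 did not pass on polysomes, at 0.22 ± 0.11, -0.20 ± 0.065 and 0.49 ± 0.19 log2 (limma adjusted p = 0.261, 0.109 and 0.167). Igf2 passed with trend and robust priors (limma adjusted p = 0.037), and Igf1 and Igf2 passed without fed polysome 1 and fasted polysome 2, chosen after seeing the data (limma adjusted p = 0.0452 and 0.0483), while Igfbp1 did not (0.48 log2, limma adjusted p = 0.0683). Igfbp2 measured 0.75 without fed polysome 3 (limma adjusted p = 0.0649). Nor did Asns (0.20 ± 0.070), Ccnd1 (0.09 ± 0.087), Afp (0.05 ± 0.066) or Alb (limma adjusted p = 0.131, 0.617, 0.685 and 0.996). Macrophage markers shifted up with 2 of 22 members higher, and 6 adjusted over the list alone (camera adjusted p = 0.00138, and adjusted p = 0.26 with an estimated correlation). These were C1qb, a complement subunit (1.42-fold), and Cd68, a lysosomal protein of macrophages (1.33-fold). Endothelial markers shifted up with 1 of 24 higher, and 5 adjusted over the list alone (camera adjusted p = 0.0283, and adjusted p = 0.405 with an estimated correlation; adjusted p = 0.103 without fed polysome 2). Megakaryocyte and platelet markers shifted down with 0 of 10 members past the limma threshold and 3 lower adjusted over the list alone (camera adjusted p = 0.00537, and adjusted p = 0.405 with an estimated correlation). Its members Gp5 and Thbs1, platelet surface and granule proteins, measured -0.42 ± 0.12 and -0.35 ± 0.090 log2. Thbs1 passed with quantile normalization and with trend and robust priors (limma adjusted p = 0.0476 and 0.0408), and Gp5 without fed polysome 1 and fasted polysome 2 (limma adjusted p = 0.0179). The 36 erythroid markers did not shift (limma camera adjusted p = 0.922), with a median of -0.003 log2 and a mean of 0.02. The 20 lists that did not pass had camera adjusted p from 0.06 to 0.968.

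The polysome count moved with single arrays, to 755 without fasted polysome 2, 516 without fed polysome 1, 11 without fasted polysome 3, 15 without fed polysome 2, 19 without fasted polysome 1 and 34 without fed polysome 3. Leaving out arrays of the other fraction gave 99 without fed total 1, 122 without fed total 2, 133 without fed total 3 and 136 without fasted total 2. It was 1263 without fed polysome 1 and fasted polysome 2 together, a choice made after seeing the data, and 309 with the replicate number as a block. It was 93 with no filter, 394 with trend and robust priors and 40 with only the arrays compared. Cpt1a, Fasn, Hsph1, Nr1d2, Rab18, Scd and Scd2 passed in all 12 leave-one-out fits. Without fasted polysome 3, limma adjusted p was 0.0638 for Vnn1, 0.0657 for Orc1, 0.0986 for Cdkl1 and Rpsa, 0.111 for Pdk4, 0.126 for Cd68 and 0.13 for Igfbp1. Without fasted polysome 1, it was 0.147 for Tp53inp1, 0.148 for Rps12, 0.155 for Doc2a, 0.157 for Cyp7a1, 0.159 for C1qb and 0.167 for Fbxo32. With no filter, the adjusted p of C1qb, Cyp7a1, Doc2a, Fbxo32, Rps12 and Tp53inp1 was 0.0592, 0.0575, 0.059, 0.0619, 0.0575 and 0.0574. With only the arrays compared, it was 0.121 for C1qb, 0.0895 for Cd68, 0.0578 for Cdkl1, 0.0688 for Cyp7a1, 0.126 for Fbxo32, 0.0941 for Igfbp1, 0.127 for Rps12, 0.0749 for Rpsa and 0.129 for Tp53inp1. Without fed polysome 1 and fasted polysome 2, Doc2a did not pass (0.0966), nor did the lists of gluconeogenesis (limma camera adjusted p = 0.257), cholesterol synthesis (0.211), urea cycle and amino acid catabolism (0.0764) and endothelial markers (0.0764).

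The fasting changes in total and polysome RNA, measured on separate arrays, ran in the same direction for most called genes. Of 259 genes past the threshold in either fraction, 249 had the same sign in both. Both tests called 51 genes, 38 higher and 13 lower, where independent lists of these sizes would share 1.2 and 0.13. Cpt1a, Vnn1, Cyp7a1, Fbxo32, Scd, Fasn, Scd2, Hsph1 and Orc1 were among the 51. Across the 10174 genes, which are not independent replicates, the changes correlated at Pearson's r = 0.591 with a slope of 0.609 of polysome on total RNA. Total and polysome arrays with the same number came from one liver as far as the data show, so the covariance of 0.0204 was also computed between different livers, where it was 0.0162 on average over 9 choices. The correlation was 0.512 with no filter on dim probes.

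**Figure D2:**
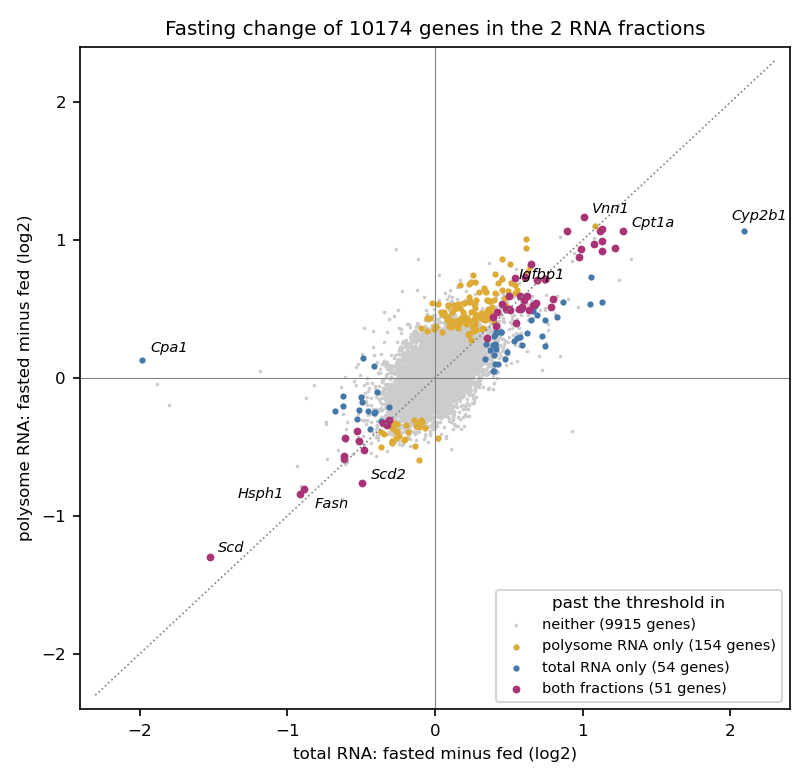
Fasted minus fed log2 change of each of 10174 genes in total RNA (horizontal) and polysome RNA (vertical), coloured by whether the gene passed the limma threshold in both fractions (51), total RNA only (54), polysome RNA only (154) or neither; the dotted line marks equal change. Scd, Fasn and Hsph1 lie at the lower left and Cpt1a and Vnn1 at the upper right, while Cpa1 lies far left near 0 in polysome RNA.

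The third comparison tested whether the fasting effect itself differed between polysome and total RNA. By limma 0 of 10174 genes passed the threshold, and the smallest adjusted p was 0.856. In this fit, which ignored the pairing, 549 genes had an unadjusted p under 0.05, where 508.7 would be expected if no gene differed. Fits that used the inferred pairing gave more such genes, 852 with each liver as a fixed block and 901 with it as a random block. In these, 1 and 0 genes passed by limma. For genes fixed in advance, the difference was -0.21 ± 0.23 log2 for Cpt1a, 0.08 ± 0.14 for Fasn, 0.18 ± 0.20 for Igfbp1, -0.25 ± 0.27 for Igfbp2, 0.15 ± 0.15 for Igf1, -0.17 ± 0.092 for Igf2 and 1.20 ± 0.58 for G6pc1, which measured 0.63 without fasted polysome 3. The difference for Igfbp2 rested on fed polysome 3, without which its fasting change on polysomes was 0.747, beside 0.743 in total RNA. With each liver as a fixed block, chosen after seeing the data, Cpa1 alone passed (2.11 log2, limma adjusted p = 0.0192), with the same difference of 2.11 without the block. Without fed polysome 1 and fasted polysome 2, also chosen afterwards, Cfap20 (0.89 log2, limma adjusted p = 0.0129) and Meg3, a maternally expressed non-coding RNA (-0.98, limma adjusted p = 0.0119), passed; these 3 genes are named because of these values.

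By camera with the preset correlation, 6 of 33 lists had a fasting effect that differed between the fractions. Each had 0 members past the limma threshold, over all genes or adjusted over the list alone, and with an estimated correlation 0 lists passed or had an unadjusted p under 0.05. The effect was more positive on polysomes for oxidative phosphorylation, B lymphoid precursor markers and the proteasome (adjusted p = 0.00557, 0.0145 and 0.0374, and adjusted p = 0.988, 0.975 and 0.988 with an estimated correlation). Its median difference was 0.10 log2 over 70 oxidative phosphorylation genes, among them the respiratory chain subunits Ndufv2 (0.39 ± 0.10) and Cox7b (0.43 ± 0.12). It was 0.25 over 7 B lymphoid markers, with Ebf1, a B lineage factor, at 0.44 ± 0.26 and Igll1 at 0.39 ± 0.19 (0.22 and 0.19 without fasted polysome 3), and 0.09 over 36 proteasome genes, with Psmb9 at 0.47 ± 0.18 and Psmb5 at 0.36 ± 0.15. The effect was more negative on polysomes for megakaryocyte markers, endothelial markers and ATF4 amino acid response genes (adjusted p = 0.0115, 0.0115 and 0.0418, and adjusted p = 0.975, 0.975 and 0.988 with an estimated correlation). Among these were Gp5 (-0.49 ± 0.17), Itgb3 (-0.39 ± 0.15), Esam (-0.35 ± 0.12), Flt4 (-0.29 ± 0.11) and Mars1 (-0.25 ± 0.13), while the ATF4 target Shmt2 went the other way (0.30 ± 0.12). The 27 other lists had adjusted p from 0.111 to 0.968. Of the 6 lists, 5 did not pass without fed polysome 1 and fasted polysome 2 together: oxidative phosphorylation (limma camera adjusted p = 0.0726), the proteasome (0.098), megakaryocyte markers (0.0766), B lymphoid markers (0.0726) and endothelial markers (0.266). The proteasome also did not pass with each liver as a fixed block (limma camera adjusted p = 0.075), with quantile normalization (0.115) or without fed polysome 1 (0.165), and the 44 ATF4 genes did not pass with no filter (0.0544), with the mean of a gene's probes (0.1) or without fed polysome 3 (0.388). Single arrays also ended the calls of oxidative phosphorylation and endothelial markers (0.105 and 0.164 without fed total 2), of B lymphoid markers (0.224 without fasted total 1) and of megakaryocyte markers (0.0639 without fed total 1). The count of lists was 2 without fed polysome 1 or fed total 2, and 3 without fasted polysome 3 or fasted total 1.

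The fourth comparison set polysome against total RNA in livers of fed dams, relative to the average transcript on each array. Dcn, the matrix proteoglycan decorin, was 5.55-fold lower (-2.47 ± 0.14 log2, limma adjusted p = 3.16e-07), and Hrg, a liver-secreted plasma glycoprotein, 3.35-fold lower (-1.75 ± 0.18, limma adjusted p = 1.12e-05). Atp5mg and Ndufb2, subunits of the ATP synthase and of complex I, were 3.10-fold and 3.08-fold higher (1.63 ± 0.11 and 1.63 ± 0.20, limma adjusted p = 6.92e-07 and 3.48e-05). The histone gene H2bc12 was 2.67-fold higher (1.42 ± 0.11, limma adjusted p = 1.56e-06). Total and polysome RNA were extracted by different methods, per the labels' protocols, so the fraction and its extraction cannot be told apart.

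In fed livers, 4425 of 10174 genes differed between the fractions, 2451 higher and 1974 lower on polysomes, and 1195 of them at least 1.5-fold. The largest rises were those of Tmem256 (3.73-fold), Med21, a Mediator subunit (3.68-fold), Crip1 (3.59-fold), Atp5mg, Ndufb2 and Psmg4, a proteasome assembly chaperone (3.05-fold). The largest falls were those of Dcn, Ccdc107 (4.30-fold), Ogn, a matrix protein like Dcn (3.90-fold), Asah1, the lysosomal ceramidase (3.93-fold), and Mmp8, a neutrophil collagenase (3.54-fold). Aspn, another matrix protein, fell from 7.58 to 5.51 log2, under the filter level of 6.07, so no fold is given. Among called genes with several probes, 55 of 214 had probes of opposite sign.

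By camera with the preset correlation, 13 of 33 lists differed between the fractions in fed livers, 5 higher and 8 lower. With an estimated correlation 0 lists passed by camera, 4 had an unadjusted p under 0.05, and the smallest adjusted p was 0.141. Of 70 oxidative phosphorylation genes, 42 were higher and 8 lower on polysomes, or 44 and 10 adjusted over the list alone (camera adjusted p = 9.29e-07, and adjusted p = 0.469 with an estimated correlation); Cox6b2 was 2.52-fold higher. Of 19 replication-dependent histones, 11 were higher, and 11 adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.553 with an estimated correlation), with H1f1 2.27-fold and Hist3h2ba 2.10-fold higher. Of 36 proteasome genes, 17 were higher and 3 lower, and the same numbers adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.553 with an estimated correlation). Of 72 cytosolic ribosomal protein genes, 26 were higher and 9 lower on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0358, and adjusted p = 0.686 with an estimated correlation); the call was lost with the mean of a gene's probes (adjusted p = 0.0991) and without fed total 3 (adjusted p = 0.0902). Of 21 transcripts with upstream open reading frames, 12 were higher and 2 lower on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0495, and adjusted p = 0.512 with an estimated correlation; adjusted p = 0.0572 with arrays centred on their median and 0.0907 without fed polysome 3).

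Lower on polysomes in fed livers were the hepatocyte secreted proteins, with 34 of 45 lower and 2 higher, or 36 and 2 adjusted over the list alone (camera adjusted p = 1.49e-10, and adjusted p = 0.333 with an estimated correlation). The complement component C9 was 3.02-fold and Azgp1 2.75-fold lower. Of 27 hepatocyte maturation genes, 13 were lower and 1 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00159, and adjusted p = 0.141 with an estimated correlation). Among them were Ugt2b1 (2.46-fold), Slc10a1, the bile acid importer (2.34-fold), and Cyp2d2 (1.92-fold). Of 22 endoplasmic reticulum chaperone and unfolded protein response genes, 18 were lower and 1 higher, or 20 and 1 adjusted over the list alone (camera adjusted p = 2.93e-07, and adjusted p = 0.469 with an estimated correlation), with Pdia4 at 1.83-fold, Sel1l at 1.67-fold and the transcription factor Xbp1 at 1.67-fold lower. Of 25 fatty acid and triglyceride synthesis genes, 11 were lower and 3 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.553 with an estimated correlation).

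Of 26 stellate and mesenchymal markers in fed livers, 20 were lower and 2 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 1.96e-09, and adjusted p = 0.141 with an estimated correlation), among them Bgn (2.89-fold) and Lum (5.62 log2 on polysomes, under the filter level of 6.07, limma adjusted p = 0.0227, and 0.0996 without fed total 1 and 0.071 with trend and robust priors), both matrix proteoglycans. Of 24 endothelial markers, 14 were lower and 2 higher, or 16 and 2 adjusted over the list alone (camera adjusted p = 1.39e-05, and adjusted p = 0.141 with an estimated correlation), with Fcgr2b at 2.54-fold and Emcn and Cdh5 at 1.79-fold and 1.78-fold lower. Of 22 macrophage markers, 13 were lower and 1 higher, or 13 and 2 adjusted over the list alone (camera adjusted p = 1.96e-05, and adjusted p = 0.141 with an estimated correlation), with Cybb at 2.31-fold, C1qb at 2.01-fold and the iron exporter Slc40a1 at 1.89-fold lower. Of 22 neutrophil and monocyte precursor markers, 12 were lower and 3 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00686, and adjusted p = 0.6 with an estimated correlation). The 36 erythroid markers did not shift (limma camera adjusted p = 0.278). The 20 lists that did not pass had camera adjusted p from 0.0522 to 0.991.

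The fifth comparison set polysome against total RNA in livers of fasted dams. Atp5mg was 3.52-fold higher (1.82 ± 0.11 log2, limma adjusted p = 4.28e-07) and Ndufb2 3.20-fold higher (1.68 ± 0.20, limma adjusted p = 2.40e-05). Dcn was 3.96-fold lower (-1.99 ± 0.14, limma adjusted p = 8.76e-07), and C9 2.92-fold lower (-1.55 ± 0.12, limma adjusted p = 1.23e-06). Cyp2e1, which rose with fasting in total RNA, was 2.62-fold lower on polysomes (-1.39 ± 0.21, limma adjusted p = 1.96e-04).

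In fasted livers, 4446 genes differed between the fractions, 2590 higher and 1856 lower on polysomes, and 1243 of them at least 1.5-fold. The largest rises were those of Med21 (4.19-fold), Tmem256 (3.92-fold), Atp5mg, Psmg4 (3.40-fold), Crip1 (3.34-fold) and Ndufb2. The largest falls were those of Ccdc107 (4.54-fold), Dcn, Asah1 (3.56-fold), Col14a1, a collagen (3.38-fold), and Olfm4 (3.36-fold). Ugt2b37, a glucuronosyltransferase, fell from 7.18 to 5.28 log2, under the filter level of 6.07, with an adjusted p of 0.0173 by limma, 0.06 without fasted polysome 2, 0.0577 without it and fed polysome 1, and 0.0627 with trend and robust priors. The fed and fasted comparisons called 1965 genes higher in both, 1493 lower in both and 0 in opposite directions, where independent lists would share 624 and 360.1. Their changes correlated across genes at r = 0.906. Among called genes with several probes, 38 of 223 had probes of opposite sign.

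By camera with the preset correlation, 13 lists differed between the fractions in fasted livers, 3 higher and 10 lower. With an estimated correlation 0 passed by camera, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0669. Of 70 oxidative phosphorylation genes, 50 were higher and 4 lower, or 51 and 5 adjusted over the list alone (camera adjusted p = 2.35e-10, and adjusted p = 0.25 with an estimated correlation), with the complex I subunit Ndufa2 at 2.33-fold higher. Of 36 proteasome genes, 23 were higher and 1 lower, or 24 and 2 adjusted over the list alone (camera adjusted p = 3.26e-04, and adjusted p = 0.338 with an estimated correlation). Of 19 histones, 13 were higher, or 14 adjusted over the list alone (camera adjusted p = 1.63e-04, and adjusted p = 0.467 with an estimated correlation), with H2bc12 and H1f1 at 2.54-fold and H4c14 at 2.24-fold higher. Of 45 hepatocyte secreted proteins, 37 were lower and 3 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 6.79e-12, and adjusted p = 0.223 with an estimated correlation), with Azgp1 at 2.27-fold and Hrg at 2.11-fold lower. Of 22 endoplasmic reticulum chaperone genes, 19 were lower and 1 higher, or 20 and 1 adjusted over the list alone (camera adjusted p = 1.09e-08, and adjusted p = 0.338 with an estimated correlation), with Hyou1 at 1.97-fold, Pdia4 at 1.89-fold and Sel1l at 1.86-fold lower.

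Hepatocyte maturation genes were lower on polysomes in fasted livers in 18 of 27 cases and higher in 1 on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 3.95e-05, and adjusted p = 0.0669 with an estimated correlation), with Ugt2b1 at 2.22-fold and Slc10a1 at 2.05-fold lower. Fatty acid and triglyceride synthesis had 10 of 25 members lower and 1 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 0.00198, and adjusted p = 0.487 with an estimated correlation). The IGF and growth hormone axis had 12 of 24 lower and 5 higher, or 12 and 6 adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.193 with an estimated correlation; adjusted p = 0.0546 with only the arrays compared and 0.0565 without fasted total 2).

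Among cell type markers in fasted livers, 17 of 26 stellate and mesenchymal genes were lower and 1 higher on either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 9.05e-09, and adjusted p = 0.107 with an estimated correlation), with Bgn at 2.79-fold and Pdgfra, a growth factor receptor, at 2.71-fold lower. Of 24 endothelial markers, 16 were lower and 1 higher, or 18 and 1 adjusted over the list alone (camera adjusted p = 2.04e-08, and adjusted p = 0.0669 with an estimated correlation), with Fcgr2b at 2.60-fold, Oit3 at 1.96-fold and Gpr182 at 1.74-fold lower. Of 22 macrophage markers, 13 were lower and 2 higher, or 13 and 3 adjusted over the list alone (camera adjusted p = 3.95e-05, and adjusted p = 0.168 with an estimated correlation), with Cybb at 2.20-fold, the mannose receptor Mrc1 at 2.10-fold and Slc40a1 at 1.88-fold lower. Of 10 megakaryocyte markers, 5 were lower, or 6 adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.391 with an estimated correlation). Of 22 neutrophil and monocyte precursor markers, 10 were lower and 3 higher, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0326, and adjusted p = 0.674 with an estimated correlation; adjusted p = 0.107 without fasted polysome 2, and 0.139 without it and fed polysome 1). The 36 erythroid markers did not shift (limma camera adjusted p = 0.297). The 20 lists that did not pass had camera adjusted p from 0.0555 to 0.74.

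Within the 9 marker lists pooled, proteins that enter the endoplasmic reticulum (secreted or membrane proteins) and other proteins had different polysome levels, a split made after the list results were seen. The median polysome minus total change over both diets was -0.58 log2 for 103 transcripts of targeted proteins, of which 92 were negative, and 0.12 for 56 others, of which 19 were negative. The difference of medians was -0.70 log2 (two-sided permutation p = 1.0e-05, the smallest value the number of permutations allows). The permutation shuffled genes across the pooled lists as if they were independent, which they are not.

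**Figure D3:**
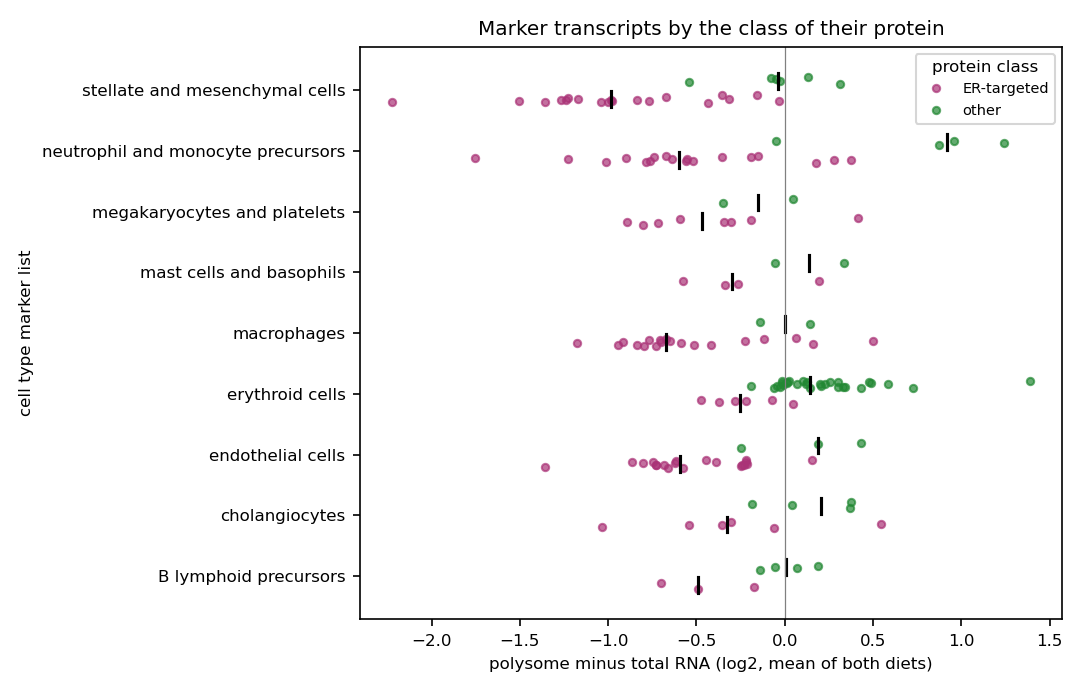
Polysome minus total RNA change (log2, mean of the fed and fasted comparisons) of cell type marker transcripts in 9 lists, with 1 point per gene, vertical bars at each median, purple for proteins targeted to the endoplasmic reticulum and green for other proteins; vertical scatter within a band carries no value. In each list the median of the targeted class lies left of the median of the other class.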

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

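Weighing the low polysome levels of proteins that enter the endoplasmic reticulum, the prediction on recovery of membrane-bound polysomes and the prediction on their loss during preparation were chosen only after the result was seen.

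For a fasting effect that differed between polysome and total RNA, 6 gene lists passed camera with the preset correlation. The adjusted p was 0.00557 for oxidative phosphorylation, 0.0115 for megakaryocyte and platelet markers, 0.0115 for endothelial markers, 0.0145 for B lymphoid precursor markers, 0.0374 for the proteasome and 0.0418 for the ATF4 amino acid response. With an estimated correlation, camera adjusted p was 0.975 to 0.988, so these calls rest on the preset correlation. Each list had 0 members past the limma threshold.

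If the yield of the polysome fraction had differed between diets, the fasting difference of each gene could follow its mean difference between polysome and total RNA. Across genes, Pearson's r between them was 0.017, within the -0.13 to 0.133 that wrong splits of the arrays gave. This r lay in the range set in advance as going against the explanation, so it argues against a difference in yield across genes as a whole. The median of 5 of the 6 lists had the sign of its polysome minus total difference, which was only -0.0118 for the ATF4 list. For the 6 lists the explanation stays open as well. If transcripts of specific pathways were loaded differently after fasting, the lists might still pass once this axis was regressed out. 4 of the 6 lists passed, but an axis this weak cannot separate the explanations.

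Signal was also present in probes that no named gene covers. Of 6470 such probes tested with limma, 4 passed for fasting in total RNA (2 higher, 2 lower), 9 for fasting in polysome RNA (7 higher, 2 lower), 1919 for polysome against total RNA in fed livers and 1746 in fasted livers. For the difference between fasting effects 0 passed by limma and 306 had an unadjusted p under 0.05.

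Of 103 cell type marker transcripts of secreted or membrane proteins, 92 were lower on polysomes. If membrane-bound polysomes were recovered poorly or carried fewer ribosomes, such transcripts might lie below other markers. The difference of medians over the pooled lists was -0.70 log2 (two-sided permutation p = 1.0e-05). This is the observation that prompted the explanation, so it is no separate support. The permutation shuffled genes across lists as if independent, which they are not. Erythroid markers made up 29 of the 56 others and 6 of the 103. Without them the difference was -0.66 log2. If the polysome preparation held fewer non-hepatocyte cells, markers that do not enter the endoplasmic reticulum could be low too. Their median in 8 non-erythroid lists was 0.0471 log2 (95% interval -0.055 to 0.19, 27 genes resampled as if independent). Fewer cells would lower both classes, so this goes against that explanation for the gap of -0.66 log2 in these lists pooled. A smaller loss of cells is not excluded. Erythroid markers of the same class had medians of 0.152 in fed and 0.135 in fasted livers, so 0 need not be the level without a loss. The pooled median cannot speak for single cell types, as the macrophage, megakaryocyte and mast cell lists held 2 such genes each. In fed livers, list medians ran from -0.134 for megakaryocyte to 0.889 for neutrophil precursor markers. If membrane-bound polysomes were lost during preparation, the loss could vary between polysome arrays; the gap varied 1.86 times as much between polysome as between total arrays, but only fed livers gave this (-0.445 to -0.237 log2 on polysomes, 0.285 to 0.363 in total RNA) and not fasted ones (-0.336 to -0.304 and 0.311 to 0.391), so the test could not tell. Transcript length was not in the tables used, so it stays open as an explanation.

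Splits of the arrays into wrong groups were also tested. With 10 splits, the share as extreme as the real one can never fall under 0.05. For fasting in total RNA, 105 genes were called in the real split and at most 1 in any other, and 18 lists against 15 (1 of 10 splits reached the real value in both cases, the real one). For fasting in polysome RNA it was 205 genes against 4 and 13 lists against 11 (1 of 10 in both). For the difference of effects it was 0 genes against 0 (10 of 10) and 6 lists against 7 (3 of 10). For polysome against total RNA it was 4425 genes against 0 (1 of 10) and 13 lists against 16 (3 of 10) in fed livers, and 4446 genes against 0 (1 of 10) and 13 lists against 16 (5 of 10) in fasted livers. Among the 4 splits that part all 3 pairs, the highest other counts were 0 genes and 11 lists in fed livers and 0 genes and 14 lists in fasted livers. List calls with the preset correlation were about as many under some wrong groupings as under the real one. However, each wrong split mixed the real groups unequally, so it kept part of the real difference and put the rest into the spread within groups. The counts of genes and lists in wrong splits therefore do not measure false calls.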

How the results depend on the processing

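The fits with fed polysome 1 and fasted polysome 2 left out together, with log2 of the value without an added 1, and with each liver as a fixed block were chosen only after the results were seen. No called list reversed its direction under any alternative, nor did any named gene that passed in the chosen fit or the alternative. For other named genes and lists, direction was not compared. Every called gene kept its sign in all 12 leave-one-out fits. For all 105 and 205 fasting calls the groups did not overlap, so leaving out 1 array could not change the sign. The same held for 4269 of 4425 and 4273 of 4446 calls for polysome against total RNA in fed and fasted livers. The kept signs therefore say little. Calls past the threshold in all 12 fits were 14 of 105 for fasting in total RNA and 9 of 205 in polysome RNA. For polysome against total RNA they were 3130 of 4425 in fed livers and 3148 of 4446 in fasted livers. The number of arrays and signal near background limit what smaller changes can show.

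With no filter on dim probes, the count for fasting was 57 in total RNA (105 in the chosen fit) and 93 in polysome RNA (205), and the correlation of the fasting effects was 0.512 (0.591); more genes, all dim, enter the fit and the adjustment. With only the arrays compared, the counts were 42 and 40, from fits with fewer arrays. With trend and robust priors the polysome count was 394; the cause was not tested. Without fed polysome 1 and fasted polysome 2 the counts were 199 in total RNA, 1263 in polysome RNA and 2 for the difference of effects, with 2 lists for that difference (6, of which 5 did not pass), 4 of the 13 polysome fasting list calls lost, neutrophil precursors lost in fasted livers, and a correlation of 0.429; the cause was not tested. With an estimated correlation, 0 lists passed by camera in each of the 5 comparisons (8, 6, 0, 4 and 6 at unadjusted p under 0.05), against 18, 13, 6, 13 and 13. The estimated correlations ran from -0.022 to 0.58, and most lay above the preset 0.01. Camera allows a list a larger error the higher this correlation is. The calls with the preset value therefore assume less correlation than was estimated for most lists.

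Leaving out 1 array at a time gave 17 to 147 genes for fasting in total RNA, 11 to 755 in polysome RNA, 0 to 0 for the difference of effects, 3661 to 4541 and 3614 to 4655 for polysome against total RNA in fed and fasted livers, and 13 to 19, 10 to 14, 2 to 8, 12 to 15 and 12 to 14 lists. The correlation ranged from 0.496 to 0.634. The cause was not tested.

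With the replicate number as a fixed replicate block, the polysome fasting count was 309 and the total RNA count 120. With each liver as a random replicate block, on the pairing of total with polysome RNA, the counts were 129, 222, 5041 and 5007, with a consensus correlation of 0.23; camera takes no random block, so lists were not run with it. With each liver as a fixed replicate block, 1 gene, Cpa1, passed for the difference of effects, and the counts for polysome against total RNA were 4871 and 4884. Blocks ended the calls of Pecam1, the IGF axis and the proteasome and added Ppargc1a, as given with those results, and changed no other call of a named gene or list.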

Other observations

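A list of exocrine pancreas genes was made only after Cpa1 was seen. Of 12 tested genes, 10 were negative in total RNA (median -0.56 log2) and 1 passed, Cpa1. Fed total 1 carried much of the fall in some of them. It measured 10.55 log2 for Ctrb1, against 7.743 and 8.529 in fed total 2 and 3. For Pnliprp1 it measured 8.881 against 6.495 and 7.271, and for Cel 7.862 against 5.985 and 6.433. Ctrb1 measured -1.80 ± 0.53 log2 (limma adjusted p = 0.112) and Cpb1 0.73 ± 0.26 (0.183). Pnliprp1, a pancreatic lipase relative, and Clps, the colipase, lay at most at 5.84 and 6.03 log2 in fasted total arrays, under the filter level of 6.07 (limma adjusted p = 0.054 and 0.105). In polysome RNA, 8 were negative (median -0.04), 0 passed by limma, and Cpa1 measured 0.13 ± 0.43.

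Nr1d2, a circadian repressor, rose 1.86-fold in total RNA (limma adjusted p = 0.00998) and 2.09-fold in polysome RNA (0.00446), and Nr1d1 rose 1.82-fold in polysome RNA (0.0126) and measured 0.46 log2 in total RNA (0.107). Cry1 fell 1.53-fold in total RNA (0.014) and 1.35-fold in polysome RNA (0.0428). If the livers differed in clock phase at harvest, 6 other genes in the phase of Nr1d1 could lie above 4 of the opposite phase. The difference of medians was 0.21 log2 in total RNA (exact p = 0.438) and -0.0575 in polysome RNA (exact p = 0.695), so the test could not tell.

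Hsph1 and its fellow chaperone gene Fkbp4 fell in both fractions, Fkbp4 by 0.53 and 0.39 log2 (limma adjusted p = 0.0181 and 0.0448). Ahsa2 and Ppid, the other heat shock genes seen before the test, fell in total RNA (limma adjusted p = 0.0137 and 0.0474). They did not pass in polysome RNA (limma adjusted p = 0.13 and 0.0583). The hypothesis of lower heat shock factor activity was tested on 15 other targets, whose median was -0.20 log2 in total RNA and -0.10 in polysome RNA, with 12 negative in each, and 0 called by limma, which fell between the values set in advance for and against it.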
